A study of Mus musculus with 6 samples.

How the data were processed

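RNA had been extracted with Trizol from the humerus shaft of mouse embryos at embryonic day 16.5, in 3 control samples and 3 samples with Stat3 removed by the Prrx1Cre driver. The labels call the controls wild type and give their genotype as 1 conditional Stat3 allele without the driver. Per the labels' protocols, complementary DNA was made with a SuperScript VILO kit and libraries with the Ion AmpliSeq mouse transcriptome panel on an Ion Chef instrument. This method amplifies 1 short target, an amplicon, for each gene, so a value reports that target and not the whole transcript. The aligner, the counter, their versions and the genome build are not given in the sources used here.

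The authors deposited RPM values, read numbers scaled to the library total on a per-million basis, for 23930 amplicons in 6 columns. Every value was a whole multiple of 1 step per column, and 100% of the values above 0 came out as whole reads within a tolerance of 0.1 read. The recovered depths were 11640697, 13376550 and 12175801 reads for control replicates 1 to 3 and 11809106, 9126493 and 9784046 reads for knockout replicates 1 to 3. A single read was worth 0.0748 to 0.110 RPM. Reads without molecular identifiers are not independent molecules, so limits taken from read numbers cover counting error only. In the deposited values, 27 gene symbols had been turned into dates, and these were read back from the amplicon names. Gene positions are those of the GENCODE M21 annotation on GRCm38, matched by symbol, which gave a position for 21334 amplicons of the table and 12342 of those tested. They are positions of the genes, and the amplicons' places within the genes are not given in the sources used here.

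Samples were grouped by genotype from the labels. The labels do not say whether the replicates were separate embryos or litters, so the p-values measure the spread between these samples, which may be partly technical. Within a group, every pair of libraries differed beyond counting noise, with a chi-square per degree of freedom of 4.54 to 7.80. Between groups this ratio was 15.2 to 20.7. Repeated libraries of 1 sample could exceed counting noise too, so the ratio does not show that the replicates were separate animals. Each library was kept as 1 replicate.

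For the main test, RPM values were converted to log2(RPM + 1) for the 12846 amplicons with a mean of at least 1 RPM. Fold changes on this scale understate the change of low genes. The groups were compared with limma version 3.58.1 in R 4.3.3, using an empirical Bayes step with a trend. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A total of 30 gene lists were written down before the data were examined. They covered STAT3 targets, osteoblasts, osteocytes, resting and proliferating chondrocytes, hypertrophic chondrocytes, osteoclasts, Wnt targets, Wnt ligands and modulators, BMP and TGF-beta targets, Hedgehog targets, Notch targets, glycolysis, oxidative phosphorylation, the cell cycle, tendon, fibroblasts, skeletal muscle, erythroid cells, macrophages, neutrophils, lymphoid cells, megakaryocytes, endothelium, pericytes, nerve, adipocytes, epidermis, the interferon response, immediate early and heat shock genes, and bone matrix processing. The 28 lists with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01 and adjusted over the lists. A second call used an estimated correlation, and fry was run beside it.

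The genes named were set by a rule made before the data were examined. It took Stat3 and, in each direction, the 10 genes with the greatest absolute log2 fold change among those past the threshold, with a mean of at least 10 RPM and non-overlapping groups. It added up to 4 members of each list, the sex-linked genes Xist, Ddx3y, Kdm5d, Eif2s3y and Uty, and the limb genes Tbx5, Tbx4 and Pitx1. Genes outside this rule are said to be so where they appear, and were picked after the values were seen.

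The alternatives were other pseudocounts (0.1 and 10 RPM), other filters, TMM, median-of-ratios and quantile scaling, other variance models, sample weights, the replicate number as a block, leaving out each library, and count tests on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. The test without genes on chromosome 17 was added after the values were seen. On simulated counts with this design and 12855 genes tested, limma recovered 14% of genes changed 1.25-fold, 74% of those changed 1.5-fold, 89.8% of those changed 2-fold and 100% of those changed 4-fold. In that simulation 4.97% of the 161 calls were false. Far fewer genes changed there than were called in the data (2142), and no scaling difference was simulated. These shares may therefore not carry over to the data. Figures were drawn with matplotlib 3.10.9. The adult globins and Isg15, Ifit3, Gapdh and Prrx1 were not analysed here.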

Results

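Gene expression was measured in the humerus shaft of mouse embryos. The study compared 3 controls with 3 embryonic samples in which the transcription factor gene Stat3 was targeted with Prrx1Cre, a driver active in limb bud mesenchyme. The purpose stated in the series was to find genes expressed differently in long bone. Depths ranged from 9126493 to 13376550 reads per library, and between 16747 and 17351 amplicons had at least 1 read. On the first principal component, which held 51.8% of the variance, the 3 controls lay between -20.6 and -14.0 and the 3 knockout libraries between 14.7 and 20.2.

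The targeted gene itself was read at nearly the same level in both groups. The Stat3 amplicon (AMPLStat3_3_1.4594, gene on chromosome 11 from 100885098 to 100939540, GRCm38) gave 208 ± 5.82 RPM in controls and 193 ± 20.1 RPM in knockouts (SD, n = 3 each). The libraries held 211, 201 and 211 RPM in controls and 208, 201 and 170 RPM in knockouts. The log2 fold change was -0.11 ± 0.08 (SE) and did not pass the test (limma, adjusted p = 0.380). An exact two-sided permutation test gave p = 0.2, where the smallest p that 3 against 3 can give is 0.1. Where this amplicon lies relative to the deleted part of the gene is not given in the sources used here, so its level checks nothing about the labels. Xist was at 638 to 809 RPM in all 6 libraries, and Ddx3y, Kdm5d, Eif2s3y and Uty had at most 5 reads in any library. The forelimb gene Tbx5 was at 69.0 ± 13.9 RPM in controls and 52.3 ± 4.81 RPM in knockouts (SD, n = 3 each, limma adjusted p = 0.0331, with overlapping groups), Tbx4 was at 11.004 ± 0.799 and 13.3 ± 2.63 RPM, and Pitx1 at 0.980 ± 0.869 and 1.20 ± 0.436 RPM.

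By camera at its preset correlation, the interferon response list was higher in knockout bone and the osteoblast, cartilage and neutrophil lists were lower. None of these calls held with an estimated correlation. The adjusted p there was 0.0574 for the interferon list, 0.0701 for osteoblasts and for neutrophils, and 0.123 for both cartilage lists. The estimate lay below the preset 0.01 for the interferon (-0.0258), osteoblast (-0.0209) and resting and proliferating (-0.0477) lists. A higher correlation is therefore not what removed those calls. The estimate lay above 0.01 for neutrophils (0.0251) and hypertrophic chondrocytes (0.0205), and whether that removed their calls was not tested. A call lost in this way does not show that a list was unchanged. Fry, which does not compare a list with other genes, gave these lists an adjusted p of 2.33e-05 to 0.00152. In all, 733 genes were higher and 1409 lower in the knockout among the 12846 tested (limma, adjusted p under 0.05), and 87 of them changed at least 2-fold, 52 higher and 35 lower. The higher share of the calls was 34.2% with the deposited scaling. It was 50.5% with TMM factors (984 higher and 966 lower), 54.3% with median-of-ratios factors (1063 and 895), 52.7% with quantile normalization (979 and 877), 53.3% with edgeR (1052 and 922) and 56.3% with DESeq2 (998 and 775). The balance of higher and lower genes therefore moved with the scaling. Group values did not overlap for 33.8% of the tested genes, where chance gives 10%. Calls fell to 481 higher and 749 lower without control replicate 1, to 442 and 729 without control replicate 2, and to 466 and 855 without knockout replicate 2.

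Among the genes with the greatest rise were Gbp4, an interferon-inducible GTPase, and the chemokines Cxcl9 and Cxcl10, which attract T cells. Gbp4 (AMPLGbp4_5_1.9897, chromosome 5, 105115767 to 105139586) went from 1.16 ± 0.502 to 29.6 ± 3.21 RPM (SD, n = 3 each), a log2 fold change of 3.85 ± 0.17 (SE, adjusted p = 1.39e-13). Cxcl10 (chromosome 5, 92346638 to 92348889) went from 1.38 ± 0.339 to 24.0 ± 2.28 RPM, with a log2 fold change of 3.40, and Cxcl9 from 2.54 ± 0.259 to 34.4 ± 3.30 RPM, with a log2 fold change of 3.32. The immunoproteasome subunit Psmb8 (log2 fold change 1.40), the peptide transporter Tap1 (1.30), the complement component C3 (1.37), the serine protease inhibitor Serpina3g (1.95) and Lacc1 (1.19) rose as well. Lrp10 (AMPLLrp10_2_1.9213, chromosome 14, 54464137 to 54471497) rose from 2.65 ± 0.899 to 45.6 ± 4.38 RPM, and its neighbour Acin1 (chromosome 14, 54642161 to 54686931) from 30.3 ± 3.89 to 100.6 ± 4.67 RPM. Gbp4 and Serpina3g belong to families of near-identical genes, so their reads may be shared with relatives.

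The greatest fall was at the amplicon of Vamp2, which encodes a vesicle fusion protein. This amplicon (AMPLVamp2_2_1.8417, chromosome 11, 69088490 to 69092384) went from 61.4 ± 3.02 to 0.413 ± 0.168 RPM (SD, n = 3 each), a log2 fold change of -5.47 ± 0.15 (SE, adjusted p = 8.07e-18). Each gene is read at 1 amplicon, so a sequence variant there would change the value without a change of the transcript's level. Mdfi, an inhibitor of MyoD-family factors, went from 37.5 ± 0.410 to 2.56 ± 0.483 RPM, and Axin1, a scaffold of the beta-catenin destruction complex, from 25.9 ± 0.642 to 1.77 ± 0.330 RPM. The histone gene Hist1h2ab, whose reads may be shared with other histone copies, fell from 255 ± 17.2 to 23.3 ± 1.09 RPM. Lower genes with known skeletal or myeloid roles were the channel gene Panx3 (-1.50 on the log2 scale), the cartilage matrix gene Matn1 (-1.28), and the neutrophil granule genes Ngp (-1.54) and S100a9 (-1.27). Hpgd (-1.25), which degrades prostaglandins, and the RNase P subunit Rpp21 (-1.51) completed the 10 lower genes. Genes changed at least 2-fold were more frequent on chromosome 17, which holds Mdfi, Axin1, Rpp21, Psmb8, Tap1 and C3, with 18 of 562 tested genes there (3.20%, Fisher's exact test, two-sided, adjusted p = 6.21e-07 over 20 chromosomes) against 0.560% on the other chromosomes together. Chromosome 3 also passed, with 11 of 605 (1.82%, adjusted p = 0.0257). Fisher's test takes genes as independent, so both p-values count clusters of related neighbours more than once. Such clusters are Gbp2, Gbp3, Gbp5 and Gbp7 on chromosome 3 and H2-Q4, H2-Q5, H2-Q6 and H2-Q7 on chromosome 17. The share of genes called at any size was 17.4% on chromosome 17 and 17.02% on chromosome 3, near the 16.7% of all tested genes.

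**Figure D1:**
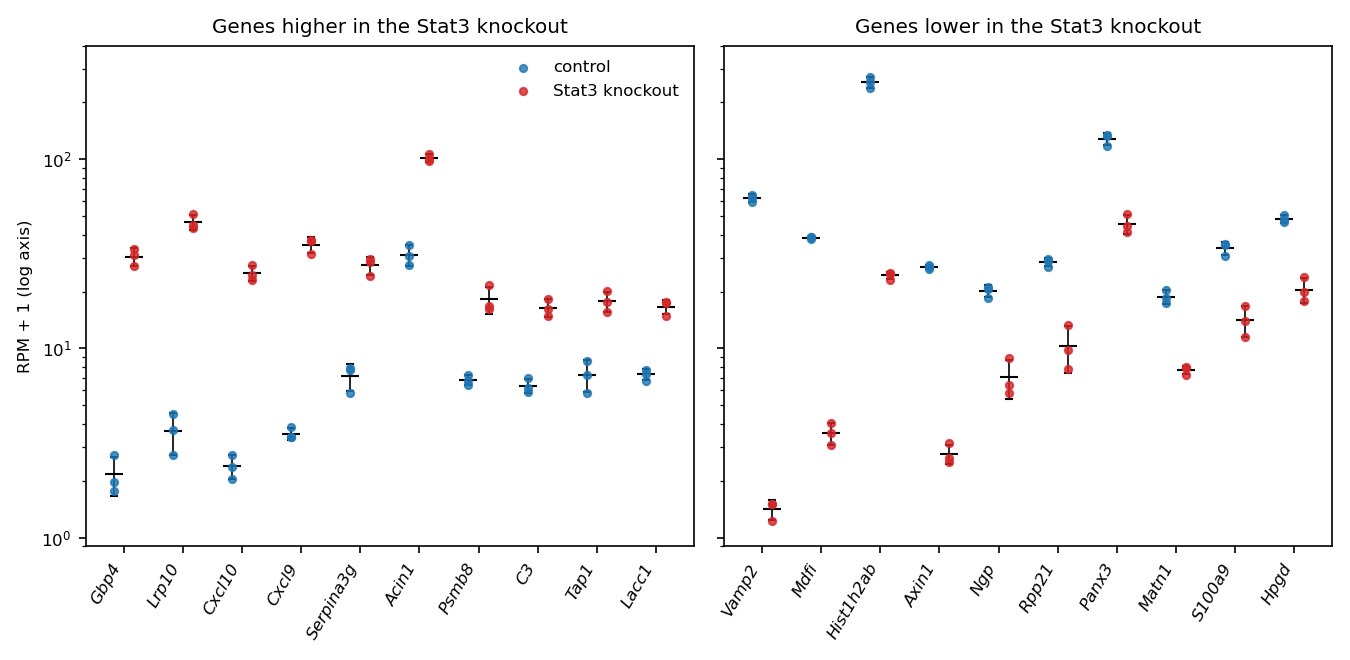
RPM + 1 of each library on a log axis for the 10 named genes higher (left) and the 10 lower (right) in the Stat3 knockout, with controls in blue and knockouts in red (n = 3 each); the black marks are the mean and SD. The groups do not overlap for any of these 20 genes, and Vamp2 falls from 61.4 to 0.413 RPM.

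The interferon response list was called higher by camera at its preset correlation, and was not called with an estimated correlation. Of its 17 measured members 9 were higher and 1 lower over all genes tested, and 10 and 1 when adjusted over the list alone. Gbp2 went from 1.44 ± 0.263 to 13.3 ± 1.44 RPM, Oasl2 from 1.45 ± 0.620 to 9.81 ± 1.05 RPM, Gbp3 from 1.96 ± 0.135 to 10.03 ± 0.718 RPM and Ifi44 from 0.893 ± 0.398 to 5.06 ± 0.245 RPM (SD, n = 3 each). The lower member was Irf9 (outside the naming rule), at -0.52 on the log2 scale. The median of the members was 0.67 on the log2 scale (camera, adjusted p = 1.06e-09), and the adjusted p was 0.0574 with an estimated correlation. None of the 11 lists called in this comparison stayed past the threshold with an estimated correlation.

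The osteoblast list was called lower by camera at its preset correlation, and was not called with an estimated correlation. Over all genes tested, 8 of its 20 measured members were lower, none was higher and 12 did not pass. Adjusted over the list alone, 9 were lower and 0 higher. The bone sialoprotein gene Ibsp fell from 4328 ± 319 to 2097 ± 66.9 RPM, the parathyroid hormone receptor gene Pth1r from 61.2 ± 7.81 to 25.8 ± 4.98 RPM, Smpd3 from 60.2 ± 2.30 to 30.5 ± 3.07 RPM, and the osteoblast transcription factor gene Sp7 from 13.6 ± 2.46 to 7.66 ± 1.35 RPM (SD, n = 3 each). The collagen genes Col1a1 and Col1a2, both outside the naming rule, did not pass the test, with log2 fold changes of -0.06 and -0.14. The list's median was -0.23 on the log2 scale (camera, adjusted p = 5.45e-06, and 0.0701 as the adjusted p with an estimated correlation). In the osteocyte list 1 of 9 members was higher and 3 were lower (2 and 3 adjusted over the list alone), among them the phosphate regulator Phex at -0.46 on the log2 scale, and the list was not called (adjusted p = 0.319). The bone matrix processing list had 4 higher and 5 lower members of 22, also adjusted over the list alone, with Alpl and Lox lower and Plod2 and Ank higher, and was not called (adjusted p = 0.978).

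Both cartilage lists were called lower by camera at its preset correlation, and neither was called with an estimated correlation. In the hypertrophic list 5 of 10 members fell and none rose, with the same counts adjusted over the list alone. Panx3 went from 127 ± 9.42 to 44.6 ± 5.16 RPM, Sgms2 from 125 ± 6.76 to 73.0 ± 8.44 RPM, and Loxl4 from 13.9 ± 1.17 to 8.46 ± 0.627 RPM (SD, n = 3 each). The collagen gene Col10a1, the classic marker of this zone and outside the naming rule, had a log2 fold change of -0.18 and did not pass (adjusted p = 0.176). The list's median was -0.29 (camera, adjusted p = 3.38e-04, and 0.123 with an estimated correlation). In the resting and proliferating list 9 of 21 members were lower and 2 higher (10 and 2 adjusted over the list alone). Matn1 fell from 17.7 ± 1.52 to 6.71 ± 0.382 RPM, Hapln1 from 38.6 ± 1.97 to 21.4 ± 1.15 RPM and the collagen-binding Comp from 29.3 ± 2.36 to 18.6 ± 2.91 RPM. This list's median was -0.22 (camera, adjusted p = 0.0151, and 0.123 with an estimated correlation).

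Genes of blood-derived cells moved in different directions. In the neutrophil list 5 of 7 members were lower (6 adjusted over the list alone) and none higher, with Ngp from 19.1 ± 1.42 to 6.04 ± 1.62 RPM, Ltf from 8.13 ± 1.30 to 2.23 ± 0.243 RPM and S100a9 from 32.8 ± 2.54 to 13.1 ± 2.66 RPM (SD, n = 3 each). Its median was -0.84 on the log2 scale (camera, adjusted p = 2.74e-06, and 0.0701 as the adjusted p with an estimated correlation). In the macrophage list 4 of 14 members were higher and 1 lower (4 and 3 adjusted over the list alone), with Cd14 from 3.005 ± 0.610 to 10.1 ± 1.63 RPM and the lysozyme gene Lyz2 from 134 ± 14.5 to 230 ± 6.91 RPM, while the receptor gene Csf1r (outside the naming rule) was lower at -0.42 (camera, adjusted p = 0.0388, and 0.156 with an estimated correlation). The osteoclast list had 4 higher and 1 lower of 19 (5 and 3 adjusted over the list alone), with the protease gene Mmp9 from 411 ± 13.0 to 671 ± 22.3 RPM and the calcitonin receptor gene Calcr from 4.49 ± 0.793 to 1.51 ± 0.288 RPM (camera, adjusted p = 0.0387, and 0.155 with an estimated correlation). Without control replicate 3 the adjusted p was 0.0533 for macrophages and 0.0726 for osteoclasts, without knockout replicate 3 it was 0.0744 for macrophages, and without knockout replicate 1 it was 0.0561 for osteoclasts.

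Further lists were called as follows. The BMP and TGF-beta target list was higher, with 5 of 16 members higher and 1 lower (6 and 1 adjusted over the list alone), including Id1 from 152 ± 18.1 to 226 ± 11.9 RPM and Pmepa1 from 34.1 ± 1.86 to 47.8 ± 3.87 RPM, while the inhibitory Smad6 fell from 14.0 ± 1.90 to 8.37 ± 2.05 RPM (camera, adjusted p = 0.00731, and 0.123 with an estimated correlation). Immediate early and heat shock genes were higher in 4 of 16 members and lower in 0, with the same counts adjusted over the list alone, for example Fos from 34.96 ± 1.62 to 45.8 ± 1.11 RPM (camera, adjusted p = 0.0304, and 0.155 with an estimated correlation). Epidermal genes were higher in 2 of 8 members, also adjusted over the list alone, and were low in both groups. Lor was at 2.69 ± 0.494 and 9.65 ± 1.35 RPM and Krt1 at 0.589 ± 0.0906 and 2.67 ± 0.968 RPM (camera, adjusted p = 0.00808, and 0.123 with an estimated correlation). Skeletal muscle genes were lower in 9 of 24 members and higher in 1 (11 and 2 adjusted over the list alone), with Ttn from 859 ± 55.0 to 584 ± 67.9 RPM and Actn2 from 784 ± 19.9 to 582 ± 11.1 RPM (camera, adjusted p = 0.00975, and 0.123 with an estimated correlation).

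**Figure D2:**
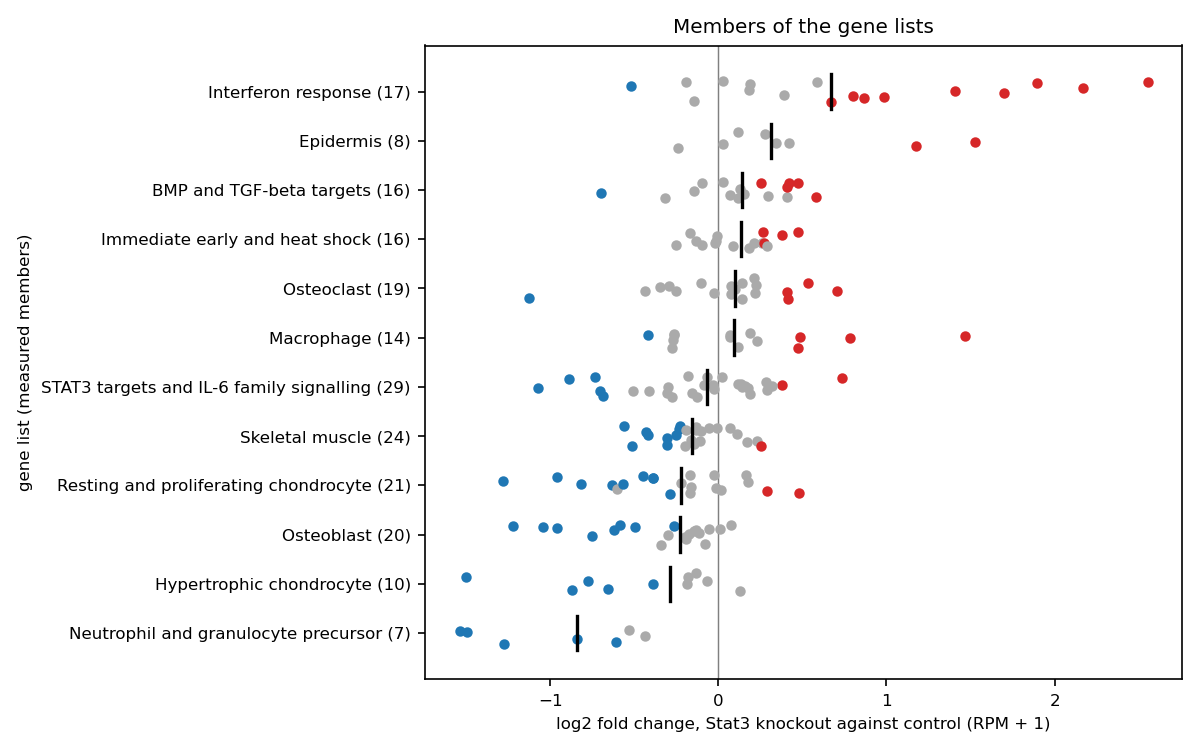
Log2 fold changes of the knockout against the control for every measured member of the 11 called lists and the STAT3 target list; red and blue points passed the test higher and lower, grey points did not, and the black bar is the list's median. The interferon list has its median at 0.67 and the neutrophil list at -0.84.

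Targets of STAT3 and genes of IL-6 family signalling went both ways. Of 29 measured members 2 were higher and 5 lower, with the same counts adjusted over the list alone, and the list was not called (camera, adjusted p = 0.904). The lower members were Lcn2 from 5.37 ± 1.23 to 2.01 ± 0.471 RPM, Hp from 12.2 ± 0.0366 to 6.12 ± 0.365 RPM, the oncostatin M receptor gene Osmr from 18.1 ± 2.59 to 10.5 ± 1.08 RPM, and Timp1 and Bcl6, which are outside the naming rule. Irf1, itself an interferon-induced factor, was higher, from 27.8 ± 0.458 to 47.1 ± 4.57 RPM, as was Fos (SD, n = 3 each). Socs3 was on the list but not among its measured members. Neutrophil granule genes fell too, and whether Lcn2 and Hp fell for the same reason was not tested.

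The Wnt target list had 3 lower and 0 higher of 21 members, also adjusted over the list alone, Dkk1 at -0.46 among them, and was not called (camera, adjusted p = 0.574). Among Wnt ligands and modulators 2 of 31 were higher and 2 lower, with Sfrp2 and Wls higher and Frzb and Sfrp4 lower (adjusted p = 0.657). Adjusted over the list alone 1 was higher and 0 lower, since Wls, Frzb and Sfrp4 each had an adjusted p of 0.0606 there. The tendon list had 2 higher and 1 lower of 11 (2 and 2 adjusted over the list alone), with the tendon genes Tnmd from 1502 ± 101.2 to 2257 ± 200 RPM and Scx from 163 ± 4.95 to 223 ± 8.19 RPM (adjusted p = 0.212). The fibroblast list had 3 higher and 4 lower of 16 (0.657), the cell cycle list 2 and 6 of 28 (0.210), oxidative phosphorylation 6 and 3 of 30 (0.157), glycolysis 3 and 2 of 23 (0.657), Hedgehog targets 1 and 2 of 11 (0.870) and Notch targets 2 and 1 of 10 (0.978), where the value in parentheses is the camera adjusted p. The endothelial list had 0 higher and 2 lower of 15 (0.870), pericytes 0 and 1 of 10 (0.870), nerve 1 and 0 of 13 (0.978), adipocytes 0 and 0 of 7 (0.978) and erythroid cells 1 and 0 of 6 (0.978). Adjusted over the list alone, the higher and lower counts were 4 and 5 for fibroblasts, 2 and 8 for the cell cycle, 1 and 3 for Hedgehog targets, 2 and 2 for Notch targets and 1 and 3 for pericytes, and were the same for the others. Camera gave an upward direction for the Wnt ligand, Notch, glycolysis, erythroid, nerve and bone matrix lists, whose medians lay below 0. The median of all genes tested was -0.06. In the endothelial and adipocyte lists the median lay above 0 and the mean below it, as it did in the fibroblast list. Lymphoid genes (2 measured) and megakaryocyte genes (3 measured) were too few to test, and none of them passed.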

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

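Among the 11084 amplicons with a mean under 1 RPM, which were outside the main comparison, 1 had no read in any control library and at least 3 reads in each knockout library. It was LOC108168394, with 5, 4 and 3 reads in knockout replicates 1 to 3, 12 in total, and 0 in the controls. The reverse pattern was seen for 4 amplicons.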

How the results depend on the processing

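All alternatives were set before the data were examined except the test without genes on chromosome 17. No result changed direction while called, and the cause of each shift below was not tested. Genes higher and lower numbered 361 and 634 when the empirical Bayes step had no trend. Lower genes numbered 775 with DESeq2, 922 with edgeR, 895 with median-of-ratios factors, 877 with quantile normalization and 869 without a filter, where 20490 genes were tested. The other scalings moved the median of all genes by less than 0.1 on the log2 scale. Leaving out 1 library gave 442 to 705 genes higher and 729 to 1324 lower. With control replicate 1 left out they numbered 481 and 749, with control replicate 2 left out 442 and 729, and with knockout replicate 2 left out 466 and 855. Fewer samples entered each of these fits, but with control replicate 3 left out they numbered 705 and 1324. With an estimated correlation 0 lists were higher and 0 lower, and fry, which does not compare a list with other genes, called 5 lists higher and 9 lower. Its lower lists included some that camera had not called. These were osteocytes (fry, adjusted p = 0.00459), Wnt targets (0.0317), the cell cycle (0.00755) and bone matrix processing (0.0469). Macrophage and osteoclast lists were also lost under 6 further alternatives each, among them the test without chromosome 17, and the skeletal muscle list without a trend.

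Of the 120 genes past the threshold that were named or picked by the rule, 40 lost it under at least 1 alternative. They were Plk1, Thy1, Dtx4, Hhip, Sfrp4, Frzb, Tbx5, Xist, Irf9, Alas2, Wls, Adgre1, Jun, Lgr6, Cdh5, Fam20c, Gas1, Jag1, Apcdd1, Ero1l, Heyl, Hsph1, Gli3, Id2, Ier2, Csf1r, Kera, Mcm2, Abcc9, Atp6v0d2, Camp, Ldha, Mef2c, Tnfrsf11a, Cyc1, Dmp1, Mfap5, Pdgfra, Pkm and Sfrp2. Uncalled throughout, Col1a1 moved from -0.06 on the log2 scale to 0.00890 with DESeq2, 0.00262 with edgeR, 0.00524 with median-of-ratios factors and between -0.109 and 0.0230 with 1 library left out, and Col1a2 from -0.14 to 0.0312 with quantile normalization. The replicate block gave 836 genes higher and 1626 lower, with 2140 of the 2142 calls shared. The numbers did not pair the samples, since the correlations of same-numbered deviations were 0.0160, -0.0454 and 0.199 and control replicate 1 correlated best with knockout replicate 2 (0.225). Depth limits values near 3 reads, which are worth 0.224 to 0.329 RPM.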

Other observations

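In this part the tests of other splits and of genes near the strongly changed amplicons were set before their results were seen, and the other tests and the antigen presentation genes were chosen after the values were seen. Bounds of the binomial test over places and of the test of other cell types were also changed after a first run, which had argued against both explanations, and the scaling test was moved from camera to fry after camera had argued against scaling too. Of 19 genes of antigen presentation, 16 were measured and 12 were higher in the knockout, with 0 lower (limma, adjusted p under 0.05). Among the higher ones, Tap1, Psmb8, H2-Aa, H2-D1 and H2-Q4 lie together on chromosome 17, between 34187553 and 35385290. The count therefore does not stand for independent places in the genome. Nlrc5, also higher, lies on chromosome 8. The places of the other higher genes are not listed here, so more of them may lie in the stretch on chromosome 17. The class I genes H2-D1 and H2-K1 went from 61.9 ± 2.45 to 114 ± 8.13 RPM and from 35.5 ± 3.11 to 64.0 ± 5.81 RPM, H2-Aa from 1.57 ± 0.323 to 4.29 ± 0.270 RPM, and the class II chaperone gene Cd74 from 8.03 ± 0.933 to 15.8 ± 2.14 RPM (SD, n = 3 each). B2m, at 307 ± 17.9 and 335 ± 25.5 RPM, did not pass (adjusted p = 0.298). The H2 genes are closely related and differ between mouse strains, so their reads are uncertain.

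A set of 4 further genes with known roles in bone was picked because they were lower, so it shows nothing about bone genes as a group. The citrate transporter gene Slc13a5 went from 80.8 ± 8.90 to 40.3 ± 4.30 RPM, Creb3l1 (a regulator of collagen secretion) from 105 ± 16.4 to 49.96 ± 10.4 RPM, the fibrillar collagen gene Col24a1 from 138 ± 8.99 to 78.2 ± 5.87 RPM, and the procollagen enhancer gene Pcolce from 462 ± 46.4 to 286 ± 13.0 RPM (SD, n = 3 each). Their calls held under TMM, median-of-ratios and quantile scaling.

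With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split called 2142 genes and 11 lists, and the highest other split called 0 genes and 1 list. In each case 1 of the 10 splits, the real one, gave as many.

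Amplicons that changed at least 4-fold numbered 19 with a position, 10 higher and 9 lower. A segment within 10 Mb of the targeted Stat3 allele is argued against as their source, since 0% of them lay there. Longer segments are not addressed, and Vamp2 and Gm12250 lie outside this window on the same chromosome. Haplotype blocks that differ between the groups remain a candidate source: 20.2% of the other tested genes within 1 Mb of them were called, just above the 95th percentile of 10000 expression-matched draws (19.9%). That excess came from the neighbours of amplicons that rose (25.6%), among them clustered interferon-inducible families. The neighbours of those that fell were called at 15.9%, near the random median of 16.3%. Of those that fell, however, Zfp52, Zfp944, Axin1, Ddr1 and Mdfi all lie on chromosome 17, between 21535539 and 47834691. The share of called neighbours within 1 Mb does not measure such a grouping. Genes changed at least 2-fold also lay close to each other, with 30 of 84 within 1 Mb of another whose symbol starts differently, against 17 at the 95th percentile of draws (permutation p = 1e-04, the smallest these draws can give), and a variant at an amplicon itself, which none of these tests address, and an effect of the knockout on these genes stay open.

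The higher interferon list could reflect more macrophages in the knockout tissue. The macrophage list's median was 0.0917 on the log2 scale, below the interferon median of 0.67 by more than the macrophage members' SD of 0.51. This SD is a spread between genes, not the error of the median. The comparison argues against more macrophages as the whole source only if both lists would rise alike with their number, which was not tested. The called members lay at 8 places in the genome, 7 higher and 1 lower, and an exact two-sided binomial test over places gave p = 0.0703. The lower place was Irf9, whose own call was lost under 9 of 20 alternatives, so this p depends on an unsteady call. Haplotype blocks with independent directions therefore cannot be told apart from a shared response by this test. A response to the loss of STAT3 itself is a hypothesis that was not tested.

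Osteoblast and hypertrophic chondrocyte lists were lower by camera at its preset correlation, and not called with an estimated correlation (adjusted p = 0.0701 and 0.123). The per-million scaling is argued against as the whole source, since under TMM, median-of-ratios and quantile scaling the medians stayed between -0.21 and -0.17 for osteoblasts and between -0.27 and -0.23 for hypertrophic chondrocytes on the log2 scale, and the largest adjusted p of fry, which does not compare a list with other genes, was 0.00156. A smaller share of bone and cartilage cells with all other cell types alike would leave the lists of the other types level or raise them. In that strict form it is argued against by the neutrophil list, picked as the lowest of 12. Of its lower members, Camp, Ngp and Ltf lie together on chromosome 9, between 109847379 and 111042767, and S100a9 lies on chromosome 3. The osteoblast gene Pth1r lies in the same stretch of chromosome 9. This argument therefore does not rest on independent places, and a haplotype block there was not tested as a source of the fall. The neutrophil median of -0.84 lay below 0 by more than its members' SD of 0.468. The other 11 medians, from -0.17 to 0.31, each lay within their members' SD of 0. That SD is the spread between genes and not the error of a median. The skeletal muscle list, with a median of -0.15, was called lower by camera at the preset correlation (adjusted p = 0.00975). It was not called with an estimated correlation (adjusted p = 0.123). A smaller share with separate changes of neutrophils and perhaps muscle, and a change of gene activity within the cells from the loss of STAT3, may each contribute. Both stay open and untested.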
